A study of Mus musculus with 2 samples.

How the data were processed

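The data were 2 droplet libraries of T cells from mouse ileum, 1 per group, made with a 10x Genomics 3' kit of version 3, per the labels' protocols. For each library the authors deposited a sparse matrix of counts, the number of UMIs per gene and barcode, with its gene and barcode lists. The deposited counts were written by Cell Ranger 7.1.0, per the file headers, and the submitters' processing notes also name mm10 and Seurat. The values are raw whole numbers, not normalised, and every deposited barcode has at least 500 UMIs. The filters applied before deposit and the version of the gene annotation are not given in the sources used here. Of the 55357 gene identifiers, 52081 were found in GENCODE M21 and 3276 were not; of 2142 identifiers that begin with ENSMUSG00002, 0 were found in it. The annotation behind the counts is therefore newer than that reference, gene names were taken from the deposited gene lists, and no coordinates are given. The 901 genes with a repeated symbol, which hold 0.00283% of UMIs, were named by their identifiers.

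Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 10% of UMIs from mitochondrial genes, which left 5665 Control and 5028 SAP barcodes. Scrublet (scanpy 1.11.5) was run per library with an expected doublet rate of 0.8% per 1000 barcodes. Its automatic threshold marked 1 Control and 0 SAP barcodes, which is under the limit of 0.5% set beforehand, so the barcodes with the top scores were removed up to the expected rate, 257 (4.54%) and 202 (4.02%). Counts were scaled to 10000 per cell and log-transformed. From 2000 variable genes, chosen without mitochondrial, ribosomal and receptor segment genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.8 (leidenalg 0.10.2) were computed over both libraries together, with no integration. Clusters were named only from marker lists written before the data were examined. A name needed at least 3 markers of 1 class among the top 10 genes by fold. A cluster was T-like with at least 3 T cell markers in 10% or more of its cells, T cell marker CPM of at least 1 part in 3 of the overall value, no larger number of markers of another class, and a depth of at least 1 part in 3 of its library's median unless T cell markers were among its top 10 genes.

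UMIs were summed over the T-like cells of each library, 15994052 in Control and 15407136 in SAP, and over each T-like cluster with at least 100 cells in each library. The SAP over Control ratio of UMIs scaled to the same library sum (CPM) was given with an exact conditional binomial 95% interval, and shares of cells with the exact Clopper-Pearson interval. A gene was eligible with 20 CPM in at least 1 library and 50 UMIs over both. With 1 library per group no test was run, no p-value was computed, and genes at 1.5-fold or 2-fold are counted only as a description of size. The named genes were the 12 highest and 12 lowest eligible genes whose interval excludes 1 and whose ratio lies on the same side of 1 in every T-like cluster with 20 or more UMIs, without mitochondrial, Rpl, Rps, Gm-numbered and Rik genes; within each cluster the 4 highest and 4 lowest were named, and 32 fixed genes and the receptor constant regions were always followed. A few genes that these rules found are left out of the text and of the figure of ratios, for a reason unrelated to their values; they stay in every count. Each of 30 gene lists was described by its median log2 ratio, its percentile among 10000 random lists matched in 20 expression bins, and the number of members beyond 1.2-fold; 6 list symbols were missing from the gene lists deposited. Lists with fewer than 3 eligible members were given no median. For shares of cells with a UMI, cells were thinned to 1000 UMIs, and a count of 0 was given the limit that 3 counts allow.

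The ratios and intervals were tested on simulated counts with the real means and depths and 200 genes changed by known folds. These counts held counting error only, the model behind the intervals, so they do not test spread between cells or libraries. The list percentiles were tested with random lists and a shifted list on the real ratios of T-like cells. In T-like cells, over 55357 genes, the intervals covered the true ratio for 95.0% of the changed genes, and 92.5% of changes of 1.2-fold and 100% of those of 1.5-fold had an interval on the right side of 1. In cluster 9, 20.9% of changes of 1.2-fold, 70.1% of 1.5-fold and 86.4% of 2-fold did. Over the 8 clusters coverage ran from 92.5% in cluster 4 to 96.5% in clusters 2 and 5, and recovery of 2-fold changes from 86.4% in cluster 9 to 98.5% in cluster 1. TMM and median-of-ratios factors were computed for the sums and checked against edgeR 4.0.16 and DESeq2 1.42.0, with no test from either. Alternatives set before the data were examined changed the cell filters, doublet removal, clustering resolution, number of variable genes, per-library centring, the definition of T-like and CD4 cells, scaling, summing, thinning and expression limit. Others, chosen after seeing the data, added the shallow cluster, subtracted the trend on transcript length (lengths from GENCODE M21, known for 99.9% of eligible genes), restricted mitochondrial share, left out the cells with most UMIs of a gene, took CD8 cells defined by UMIs, and took list medians in CD4 cells defined by UMIs or in cluster 9 without cells that held transcripts of other T cell classes.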

Results

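Single-cell transcriptomes were measured in T cells of mouse ileum in 2 libraries, 1 labelled Control and 1 labelled SAP. In the study's design, dendritic cells were treated with bacteriophages taken from healthy mice or from SAP mice, and were then cultured together with gut T cells of GF mice. T cells that had touched an antigen-presenting dendritic cell were tagged on their surface with fucosyl-biotin by the FucoID proximity reaction, so that they could be sorted away from bystander cells. The labels give only the words Control and SAP for the libraries, so Control was taken as the library set against SAP and nothing more. It is not stated whether the sequenced cells are the tagged fraction. The question of the comparison is how the T cells of the SAP library differ from those of the Control library. The Control library held 5737 barcodes and 19142384 UMIs, with a median of 3121 UMIs per barcode. The SAP library held 5203 barcodes and 19144320 UMIs, with a median of 3351. The labels state a target of 5000 cells per library. With 1 library per group there is no replicate check of any difference and no test was made; every 95% interval covers counting error only.

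After filtering and doublet removal 5408 Control cells and 4826 SAP cells remained. Barcodes with more than 10% mitochondrial UMIs made up 1.10% of the Control library and 3.13% of the SAP library, and the median mitochondrial share of the retained cells was 1.19% and 1.49%. Joint clustering gave 12 clusters, of which 8 were T-like. T-like cells were 86.8% of Control cells (exact interval 85.9 to 87.7) and 85.1% of SAP cells (84.1 to 86.1). Cluster 3, a shallow cluster of 1248 cells with a median of 1043.5 UMIs and 3.97% mitochondrial UMIs, was kept out of the T-like cells by the depth rule alone; it held 11.6% of Control cells and 12.8% of SAP cells. The other small clusters were cluster 10, which stayed unnamed, cluster 11, which was proliferating-like with Mki67, Birc5 and Stmn1 and held 39 Control and 20 SAP cells, and cluster 12, with 5 cells from each library. The rule named cluster 12 plasma-like by Igkc, Ighg2b, Jchain and Igha. Jchain was found in 30% of its cells, and the B cell markers Cd74 and Cd79a in 100% and 60%. Over all cells Igkc stood at 909 CPM in Control and 5.24 CPM in SAP, so the name may not hold for the SAP cells. No dendritic-like cluster was found.

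The T-like cells of both libraries carried the transcripts of cytotoxic gut T cells. Ccl5, a chemokine gene, reached 36252 CPM in Control and 33217 CPM in SAP, and Gzma, which encodes a granzyme, 21641 and 21232 CPM. Cd8a was at 576 and 634 CPM, Itgae, the integrin chain that binds epithelial E-cadherin, at 522 and 583 CPM, and Trdc, the delta chain constant region, at 494 and 526 CPM, while Cd4 was at 22.8 and 24.4 CPM. By UMIs alone, cells with Cd8a or Cd8b1 and no Cd4 were 68.3% of Control (66.9 to 69.6) and 70.2% of SAP T-like cells (68.8 to 71.6). Cells with Cd4 and neither Cd8 chain were 3.83% (3.30 to 4.42) and 4.02% (3.44 to 4.66). These shares are not thinned, the SAP cells are deeper, and a UMI of Cd8a was also found in 24.4% of Control and 26.4% of SAP cells of cluster 10, so they describe each library and not a difference. Cluster 9 was the only T-like cluster with a class name, CD4 T-like, resting on 5 markers. It held 6.90% of Control T-like cells (6.19 to 7.66) and 6.77% of SAP T-like cells (6.02 to 7.58).

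Among the T-like clusters that the markers left unnamed, clusters 1 and 4 took larger shares of the SAP library and clusters 2 and 6 smaller ones. Cluster 1 held 24.3% of Control T-like cells (23.1 to 25.6) and 28.8% of SAP T-like cells (27.4 to 30.2), and cluster 4 held 12.1% (11.2 to 13.1) and 14.9% (13.9 to 16.1). Cluster 2 held 15.7% (14.7 to 16.8) and 12.8% (11.8 to 13.9), and cluster 6 held 11.6% (10.7 to 12.6) and 8.74% (7.89 to 9.64). In clusters 5 and 7 the intervals of the libraries overlapped, at 12.9% and 12.3% and at 7.75% and 8.47%. Cluster 8 was left out of this comparison because 2 of its 10 leading genes differed by at least 1.5-fold between the libraries in the other T-like cells. When principal components were centred per library, the log2 ratio of SAP to Control was 0.04 for the best match of cluster 4, against 0.30 in the main clustering, and 0.10 against 0.24 for cluster 1. Cluster 4 also had the highest median mitochondrial share of the T-like clusters, 1.76%.

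**Figure D1:**
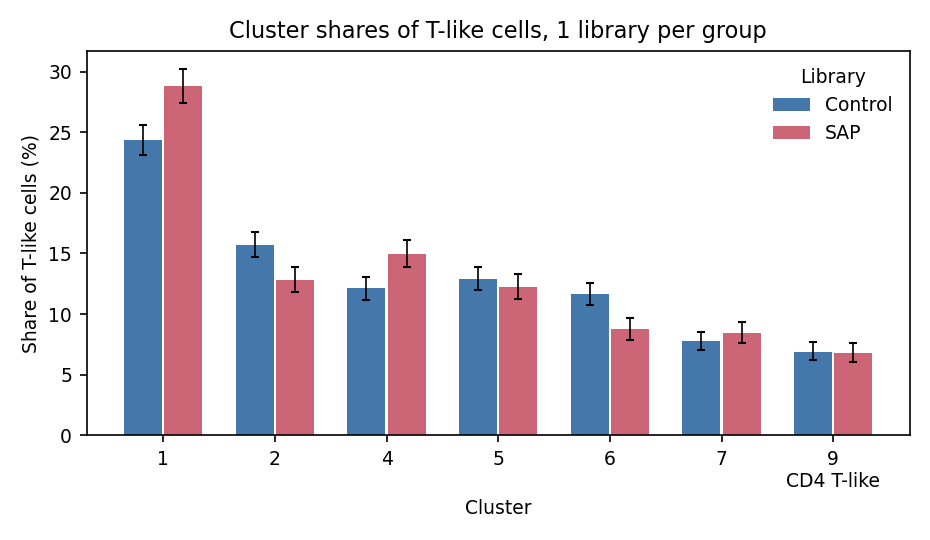
Bars give the share (%) of each library's T-like cells in each numbered cluster, blue for Control and red for SAP, with exact 95% binomial intervals as error bars (counting error only, 1 library per group). Cluster 1 holds 24.3% of Control and 28.8% of SAP T-like cells, and the CD4 T-like cluster 9 holds 6.90% and 6.77%.

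Summed over all T-like cells, expression in the libraries was nearly equal. Of 5399 eligible genes, 4911 (91.0%) lay within 1.2-fold of each other. At least 1.5-fold apart were 10 genes, 8 higher and 2 lower in the SAP library, and no gene reached 2-fold. The median log2 ratio was 0.06. In 20 simulated pairs of libraries with the same depth and only counting error, no gene reached 1.5-fold. The split of higher and lower genes hung on the scaling: it was 2 higher and 6 lower with TMM factors and 5 higher and 4 lower with median-of-ratios factors.

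**Figure D2:**
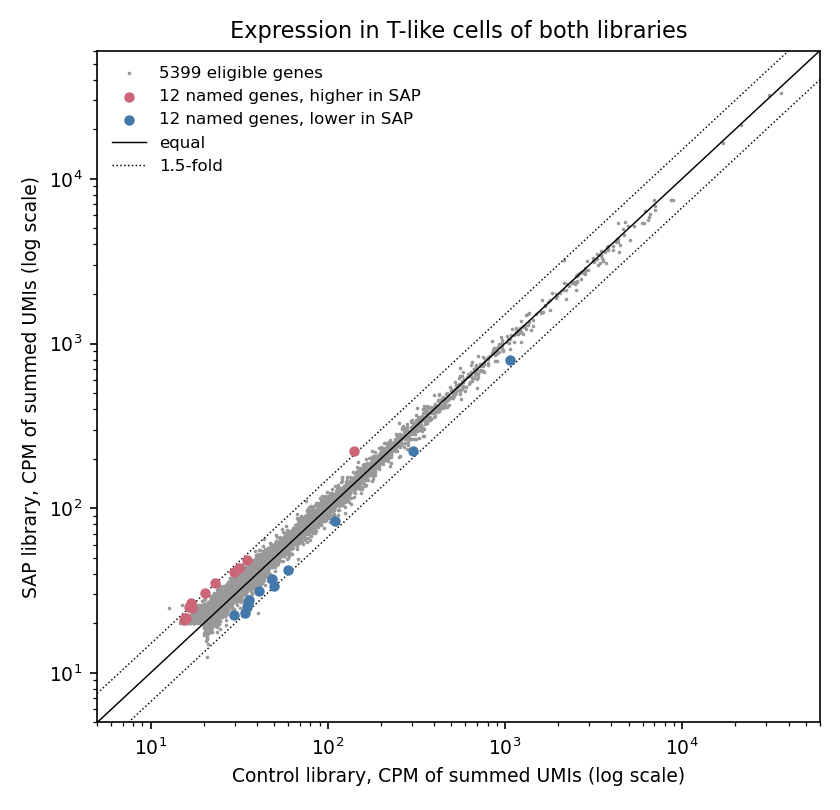
Each grey point is 1 of 5399 eligible genes, placed by its CPM in T-like cells of the Control library (x axis, log scale) and of the SAP library (y axis, log scale); the 12 genes found by the fixed rule as higher in SAP are red and the 12 lower are blue. Points lie along the line of equal expression, with 10 genes at or beyond the dotted 1.5-fold lines and none at 2-fold.

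Among the genes found by the fixed rule, the largest ratios upward belonged mostly to genes of low abundance. The rule left out other genes that were at least 1.5-fold apart, and no gene it found as lower reached 1.5-fold. Mir6236, annotated as a microRNA gene, stood at 141 CPM in Control and 223 CPM in SAP, a ratio of 1.58, and was also the leading gene of the shallow cluster 3. A UMI of Mir6236 was found in 26.3% and 38.4% of cells, shares that are not thinned although the SAP cells are deeper. Ddhd1, a phospholipase gene, had a ratio of 1.58 (1.35 to 1.85), the histone gene H2ac6 1.52 (1.30 to 1.79), Nopchap1 1.52 (1.33 to 1.74) and Jade1, a subunit of a histone acetyltransferase complex, 1.51 (1.31 to 1.75). H2ac6 is also among the leading genes of cluster 8. Cdkal1, which encodes a tRNA-modifying enzyme, had a ratio of 1.43, Tex9 1.38, Zfp280d 1.38, the phosphatase gene Cdc14a 1.38, Kansl3, a subunit of another acetyltransferase complex, 1.37, Ebag9 1.37 and the solute carrier Slc22a15 1.37. Apart from Mir6236, these genes lay between 15.4 and 35.3 CPM in Control. The rule asked for a ratio above 1 in every T-like cluster where the gene was measured, which was 7 or 8 clusters.

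Snhg9, a host gene of small nucleolar RNA, stood at 49.8 CPM in Control and 33.9 CPM in SAP, a ratio of 0.681 (0.608 to 0.761), and Igsf8 had a ratio of 0.684 (0.597 to 0.784). Mir142hg, a microRNA host transcript, had a ratio of 0.703. Clec2d, which encodes a ligand of an NK cell receptor, stood at 305 CPM in Control and 222 CPM in SAP, a ratio of 0.727 (0.696 to 0.759). Cox16, a cytochrome oxidase assembly factor, had a ratio of 0.756, the translocon subunit Sec61g 0.761, the mitochondrial import subunit Tomm6 0.762, Phf23 0.766, the noncoding Gt(ROSA)26Sor 0.775 and the RNA polymerase subunit Polr2l 0.777. Across all eligible genes, the median log2 ratio ran from -0.02 in the 5% of genes with the shortest transcripts to 0.12 in the 5% with the longest. The cytokine gene Il17a, also in this group, had a ratio of 0.715 (0.626 to 0.815), but it was measured in cluster 9 alone and rested on 33 cells in each library, with 85 of 562 Control UMIs and 142 of 387 SAP UMIs in 1 cell.

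**Figure D3:**
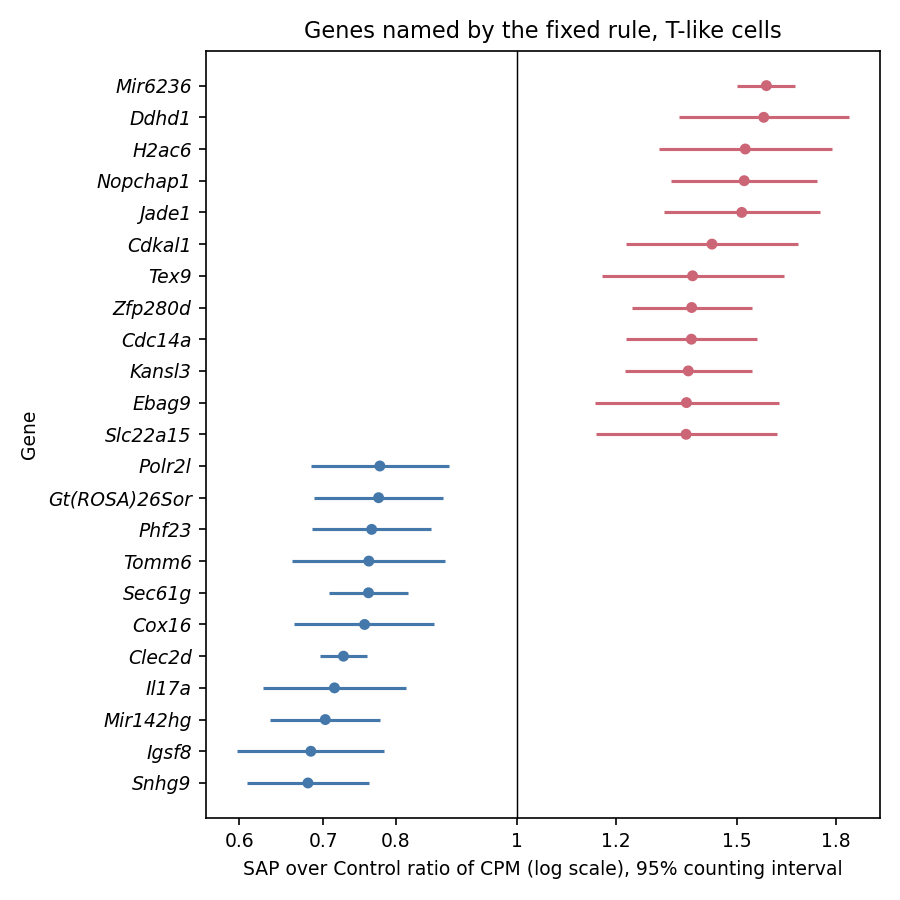
Points give the SAP over Control ratio of CPM (log scale) in T-like cells for 23 of the 24 genes found by the fixed rule, with 95% counting intervals as bars. Ratios run from 0.681 for Snhg9 to 1.58 for Mir6236; the rule left out genes whose interval holds 1.

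Most genes that define T cell states differed little. Bcl6, a transcriptional repressor, was lower in SAP in 8 of 8 clusters, at 76.2 CPM in Control and 62.0 CPM in SAP, a ratio of 0.813 (0.746 to 0.886), and Itgae was higher in 8 of 8 clusters, a ratio of 1.12 (1.09 to 1.15). Cd8a had a ratio of 1.10 (1.07 to 1.13) and Cd8b1 1.12 (1.03 to 1.21). The interferon-induced gene Isg15 had a ratio of 0.873 (0.835 to 0.913), Tcf7 0.883 (0.808 to 0.964), the gut homing receptor Ccr9 0.923 (0.873 to 0.975) and the Th1 regulator Tbx21 0.915 (0.851 to 0.983). The effector and activation genes lay close to 1: Ifng 0.964, Gzmb 0.975, Gzma 0.981, Prf1 1.03, Tnf 1.11, Cd69 0.968, Nr4a1 0.997, Lag3 0.972 and Ctla4 1.01, with Gata3 at 1.07 and Cd4 at 1.07. Below the expression limit in T-like cells, Il2 had 52 UMIs in Control and 81 in SAP, a ratio of 1.62 (1.13 to 2.34), Il10 had 128 and 74, a ratio of 0.600 (0.445 to 0.805), and Il22 had 222 and 49, a ratio of 0.229 (0.165 to 0.313). A few cells carry the last 2: Il10 was found in 39 Control and 38 SAP cells and Il22 in 23 and 19, with 96 Control UMIs of Il22 in 1 cell. Foxp3 had a ratio of 0.623 (0.359 to 1.06), the intervals of Pdcd1, Ccr7, Mki67 and Ifit3 also held 1, and Fut7 had no UMI. The Mki67 value leaves out the proliferating-like cluster 11, which was not T-like by the rule although its T cell markers stood at 8101.5 CPM. That cluster held 0.721% of Control and 0.414% of SAP cells, a ratio of 0.575 (0.318 to 1.01). The T cell receptor constant regions were close as well, with ratios of 0.964 for Trac, 1.04 for Trbc1, 0.980 for Trbc2, 1.07 for Trdc, 1.05 for Trgc1, 1.16 (1.09 to 1.23) for Trgc2 and 1.04 for Trgc4.

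Shares of cells with a UMI were taken after each cell was thinned to 1000 UMIs, which left out 203 Control and 192 SAP T-like cells. Itgae was found in 39.0% of Control T-like cells (37.6 to 40.5) and 41.6% of SAP T-like cells (40.1 to 43.2), against 70.6% and 74.9% without thinning. Bcl6 was found in 7.06% (6.32 to 7.85) and 5.23% (4.56 to 5.98), Isg15 in 935 of 4492 and 705 of 3917 cells, and Gzma in 85.5% (84.4 to 86.5) and 82.0% (80.7 to 83.2), against 18.5% and 16.3%, 41.9% and 39.9%, and 91.0% and 89.0% unthinned. Ifng was found in 12.3% and 12.9%, Cd8a in 39.6% and 40.4%, Cd69 in 35.0% and 35.5%, and Cd4 in 90 cells of each library. For Il22, at 0.356% (0.204 to 0.578) and 0.255% (0.122 to 0.469), and Il10, at 0.423% and 0.357%, the intervals overlapped. Cluster 10, whose leading genes held no T cell marker, was taken as the background, which may hold free RNA and doublets; its thinned shares in Control and SAP were 25.8% and 14.3% for Itgae, 3.23% and 3.17% for Bcl6, 9.68% and 4.76% for Isg15, 51.6% and 31.7% for Gzma, 6.45% and 1.59% for Ifng, 19.4% and 9.52% for Cd8a, 12.9% and 15.9% for Cd69 and 0 for Cd4, over 31 and 63 cells. Before thinning, cluster 10 had medians of 3258 and 19538 UMIs per cell, against 3278 and 3607 in T-like cells, so the SAP background is that of much deeper cells. Unthinned, its shares were 56.1% and 61.1% for Itgae, 14.6% and 29.2% for Bcl6, 14.6% and 12.5% for Isg15 and 78.0% and 80.6% for Gzma, and for Bcl6 in SAP the background lay above the T-like share. The cells of cluster 10 may also make such transcripts themselves, so its shares do not measure free RNA alone. Fut7 was found in 0 of 4492 Control and 0 of 3917 SAP cells, which allows shares of up to 0.0668% and 0.0766%.

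Of the 30 fixed gene lists, 29 had at least 3 measured members, and the medians of 6 lay outside the central 95% of random lists of matched size and expression, all by small amounts. The mitochondrially encoded genes had a median ratio of 1.15 (99.99th percentile); of 11 measured members 2 were over 1.2-fold higher, mt-Co3 at 1.29 and mt-Nd4 at 1.27, and mt-Atp8 was lower at 0.791. The immediate early and dissociation stress genes had a median ratio of 1.08 (100th percentile), with Fosb at 1.28, Hspa1a at 1.18 and Fos at 1.16, and 18 of 19 members within 1.2-fold. The mitochondrial share of the SAP library was also higher, with a median of 1.38% against 1.12% in T-like cells. Genes of the mitochondrially encoded list enter that share, so this list is not a separate observation. The immediate early list sits beside it. Below the random range were NF-kB and TNF signalling with a median ratio of 0.962 (percentile 0.615; Ltb 0.824, Bcl2a1b 0.858, Nfkbia 0.903), anti-apoptosis and survival with 0.948 (percentile 1; Bcl2a1d 0.888, Birc2 0.899, against Bcl2 at 1.19), apoptosis and p53 with 0.963 (percentile 0.480) and T follicular helper with 0.919 (percentile 1.01, 3 members, Bcl6 the lowest). In the first 2 of these, 16 of 17 and 9 of 9 members lay within 1.2-fold. In CD4 T-like cells alone the medians of NF-kB and TNF signalling and of anti-apoptosis and survival turned to the other side of 0, at log2 0.01 and 0.09.

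The lists that follow lay inside the random range in all T-like cells. TCR signal and early activation had a median ratio of 0.978 (3.25th percentile), Th1 0.969 (3.23), Th17 0.962 (4.38), cytokines and chemokines 0.964 (3.31), type I interferon response 1.02 (33.9), interferon gamma response 1.04 (38.2), antiviral and nucleic acid sensing 1.04 (39.3), cytotoxic granule and NK receptor 1.02 (76.1) and inhibitory receptor and exhaustion 1.01 (41.2). Within these lists Tnfrsf9, a costimulatory receptor, had a ratio of 0.802 (0.748 to 0.861), and Cd160, which encodes a receptor of cytotoxic cells, 1.25 (1.19 to 1.32). The cholesterol synthesis genes had a median ratio of 1.11, just inside the range (97.36th percentile), with 4 of 16 over 1.2-fold higher, among them Msmo1 at 1.33 and Idi1 at 1.28; in CD8 cells taken by UMIs, chosen after seeing the data, it lay outside, at log2 0.16 (percentile 99.05). Of the fucosylation genes 5 were measured, with a median ratio of 1.03 (27.3), St3gal6 the highest at 27.4 CPM in Control and 32.8 CPM in SAP and B4galt1 the lowest with a ratio of 0.875. Medians this close to 1 changed side with the scaling: with TMM factors those of type I interferon, interferon gamma, antiviral, cytotoxic, exhaustion and fucosylation genes were below 0 on the log2 scale.

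**Figure D4:**
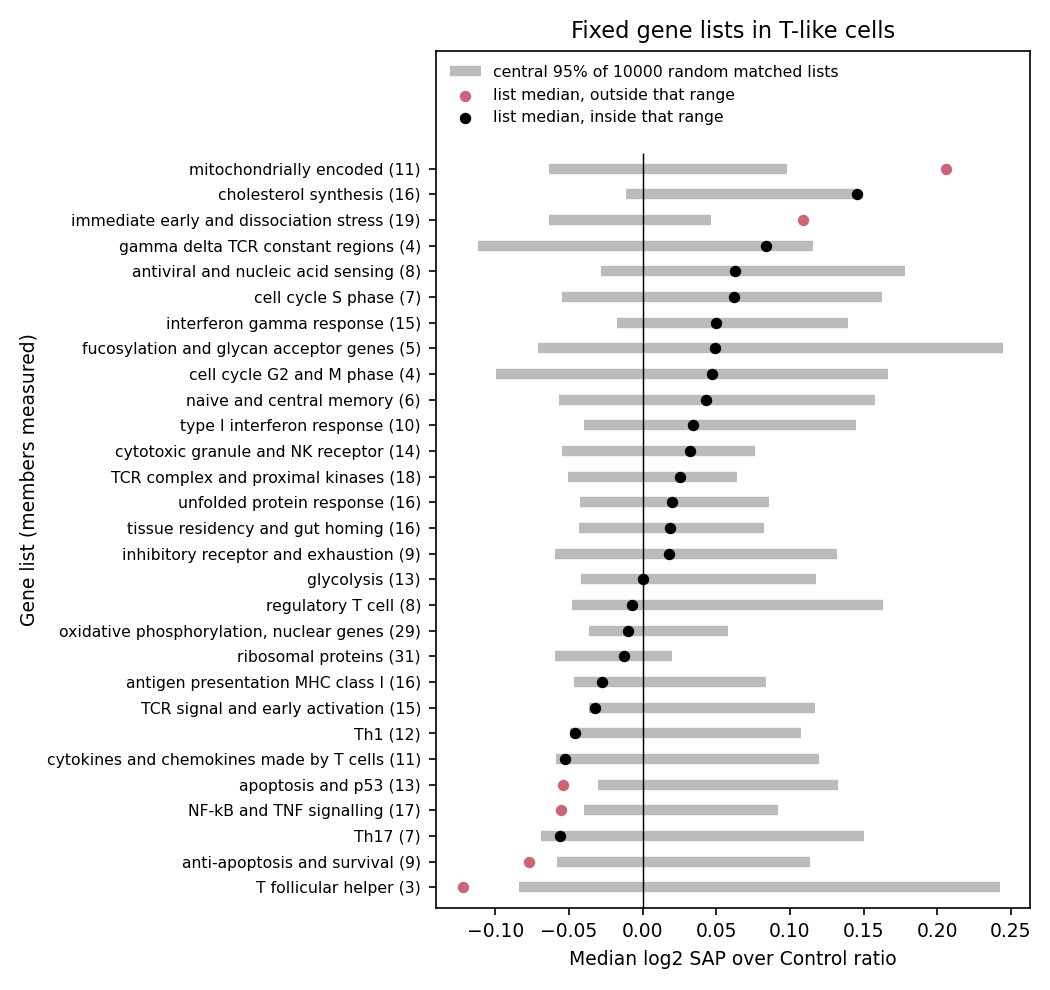
Points give the median log2 SAP over Control ratio of the measured members of each fixed gene list in T-like cells, red where it lies outside the central 95% of 10000 random matched lists (grey bars) and black where it lies inside. The mitochondrially encoded and immediate early lists lie above their bars, at 0.21 and 0.11, and 4 lists lie below theirs.

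Within the numbered clusters ratios spread further, and many of the largest came from very few cells. Counting error makes up part of this spread, and more of it in some clusters than in others. In cluster 8, 380 eligible genes were at least 1.5-fold apart, against a mean of 248 from counting error alone. In cluster 1 these numbers were 62 and 14.5. The intervals of the genes named within clusters are not adjusted for the number of genes compared. In cluster 9, the CD4 T-like cells, 38 genes were at least 2-fold higher and 14 at least 2-fold lower of 4431 eligible; counting error alone gave a mean of 12.5 such genes in both directions over 20 simulated pairs. Tnfsf11, which encodes the cytokine RANKL, was higher in SAP, with 23 UMIs in 18 of 324 Control cells and 69 UMIs in 36 of 278 SAP cells, a ratio of 3.19 (1.97 to 5.36). Gabpa, an ETS family transcription factor, had a ratio of 2.89 (1.53 to 5.77), Trgc1 3.32 (1.89 to 6.11, with 23 of 53 SAP UMIs in 1 cell), and Penk, the enkephalin precursor, 4.94 (2.90 to 8.91, with 54 of 79 SAP UMIs in 1 cell). The lowest were chemokine and cytokine genes, each carried by few cells. Il22 had 218 UMIs in 21 Control cells and 47 UMIs in 17 SAP cells, a ratio of 0.229 (0.164 to 0.316), with 96 UMIs in 1 Control cell; when CD4 cells were taken by UMIs instead, its log2 ratio was 0.48, on the other side of 0. Ccl4 had a ratio of 0.258 (0.172 to 0.378), with 116 of its 140 Control UMIs in 1 cell. Ccl20 had 60 UMIs in 7 Control cells, 34 of them in 1 cell, and 2 UMIs in 2 SAP cells. Its ratio was 0.0355 (0.00420 to 0.134). Cxcl2 had 55 UMIs in 7 Control cells, 35 of them in 1 cell, and none in SAP. Against a floor of 3 counts it was 17.2-fold lower in SAP, and its counting interval reached a ratio of 0.0738. Without the 3 cells with most UMIs of each gene, 6 Control UMIs of Ccl20 and 7 of Cxcl2 were left. The intervals then reached ratios of 0.904 and 0.738.

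In the largest cluster, cluster 1, 1 of 5838 eligible genes reached 2-fold. Phykpl had a ratio of 2.10 (1.53 to 2.92), N4bp2 1.75 and Bspry 1.71 (1.21 to 2.42), and Polr3f, an RNA polymerase subunit, stood at 11.6 CPM in Control and 23.2 CPM in SAP. Snhg9 had a ratio of 0.550 (0.442 to 0.684), Cox16 0.571, Galnt10 0.617 and the hyaluronan receptor Cd44 0.618 (0.447 to 0.849). In cluster 2 the NK-type receptor gene Klra7 was higher in SAP, with 83 UMIs in 22 Control cells and 164 in 26 SAP cells, a ratio of 2.51 (1.92 to 3.31), beside Klf4 at 2.92, Trappc5 at 2.54 and Ccdc84 at 2.48. Its lowest genes, Defa30, Fabp1, Fabp2 and Defa22, are epithelial transcripts with 97, 59, 72 and 66 Control UMIs, each gene's in 1 cell. In cluster 8 Klra6 had a ratio of 2.91 (1.59 to 5.59), Ankib1 2.81, H2-K2 2.53 and Senp3 2.33, and Klra3 0.448 (0.245 to 0.785), H2ac24 0.408, Paip2b 0.379 (23 of 60 Control UMIs in 1 cell) and Terf2ip 0.353.

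In the other clusters the same rule again met transcripts found mostly in 1 cell beside broadly found genes. Cluster 4 had Neurog3, a regulator of enteroendocrine cells, with 89 UMIs in 1 SAP cell and none in Control, and Mcpt1 and Mcpt2, mast cell proteases, had 153 and 70 UMIs in 1 Control cell of cluster 7 and none in SAP. Igha in cluster 5 had 90 of 96 SAP UMIs in 1 cell, S100a6 there 49 of 69, and Mcm8 in cluster 7 had 84 of 85 Control UMIs in 1 cell. Igkc in cluster 6 had 49 UMIs in 19 Control cells and 1 in SAP; over all cells it was at 909 CPM in Control and 5.24 CPM in SAP. Cluster 4 also had Sox4 at a ratio of 5.88 (83 of 125 SAP UMIs in 1 cell), Stmn1 at 3.33 (41 of 63 SAP UMIs in 1 cell) and Olfr655 at 0.128 (29 of 53 Control UMIs in 1 cell). Spread over more cells there were Tpd52 at 3.18, Ghdc at 0.282, Tlcd2 at 0.308 and Katnip at 0.370. Cluster 5 had Rdm1 and Tmem156 at 2.59, Tbc1d4 at 0.305, Ppp1r9b at 0.413, Zbtb2 at 0.415 and Zfp407 at 0.419. Cluster 6 had Vmn2r96 at 2.55 (17 of 42 SAP UMIs in 1 cell), Jade1 at 2.53, Mbp at 2.33, Cenpc1 at 2.30, Polr1c at 0.371, Ctdp1 at 0.414 and Bola1 at 0.435. Cluster 7 had Lgals1 at 3.97, Sf3a3 at 2.78, Sympk at 2.74, Tesk1 at 2.68 and Ctnnbl1 at 0.417. Over the 8 clusters, 27 of 32 genes named as higher and 23 of 32 named as lower kept an interval on the same side of 1 when the 3 cells with most UMIs of the gene were left out of each library.

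Markers of other cell types were summed in T-like cells of both libraries. ILC3 markers stood at 507 CPM in Control and 454 CPM in SAP, a ratio of 0.897 (0.869 to 0.926), led by Ltb at 177 and 146 CPM, ILC2 markers at 241 and 227 CPM and NK cell and ILC1 markers at 65.8 and 65.3 CPM. Dendritic cell markers summed to 258 CPM in Control and 261 CPM in SAP, a ratio of 1.01 (0.969 to 1.06), of which Cst3 made up 118 and 116 CPM. B cell markers had a ratio of 0.932 (0.870 to 0.998), plasma cell markers 0.912 (0.874 to 0.950), macrophage and monocyte markers, at 556 and 494 CPM, 0.890 (0.863 to 0.918, mostly Plac8), mast cell markers 0.785 (0.733 to 0.841) and epithelial markers 0.860 (0.806 to 0.918), led by Epcam at 75.2 and 76.7 CPM. Single Control cells weigh on the last 2 ratios. Of 1918 Control UMIs of mast cell markers, 153 of Mcpt1 and 70 of Mcpt2 were each in 1 cell of cluster 7. The leading mast cell marker, Kit, stood at 92.1 and 82.4 CPM. Of 2054 Control UMIs of epithelial markers, 97 of Defa30, 72 of Fabp2 and 59 of Fabp1 were each in 1 cell of cluster 2. Over all cells the B cell ratio was 0.115 (0.110 to 0.121) and the plasma cell ratio 0.177 (0.171 to 0.182), both led in Control by Igkc. Igkc alone made up 909 of the 1022 CPM of B cell markers in Control and 5.24 of 118 CPM in SAP. Igkc was the leading gene of cluster 12, which held 5 cells from each library. Few cells may therefore set these ratios, which do not measure numbers of B cells. Fibroblast and stroma markers were higher in SAP, with a ratio of 1.23 (1.06 to 1.42), as were red blood cell markers with 1.07 (1.02 to 1.12), mostly Car2, while endothelial markers stood at 27.3 and 31.1 CPM. Neutrophil markers stood at 3.69 and 2.86 CPM. The epithelial ratio turned above 1 when doublets were kept, at log2 0.20, and over all cells it was 1.59 (1.52 to 1.66), led by Krt18, of which cluster 10 held 1042 of 1109 Control UMIs and 2403 of 2450 SAP UMIs. Mitochondrial ribosomal RNA genes took 0.694% of T-like UMIs in Control and 0.867% in SAP, mitochondrial protein genes 0.488% and 0.555%, and genes of cytoplasmic ribosomal proteins 24.2% and 23.1%; the first 2 were higher, and the last lower, in SAP in 8 of 8 clusters.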

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

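All tests in this part were chosen only after the results were seen; for the 24 genes the bounds were set before the values of the tests were computed.

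Cluster 10 held 72 of 4826 SAP cells, 1.49% (1.17 to 1.88), and 41 of 5408 Control cells, 0.758% (0.545 to 1.03), and stood out as a signal outside the T-like cells that was higher in SAP than in Control. Processed pseudogenes took 26.0% of its UMIs, 78.8 times their share in T-like cells, and its leading genes included Folr1 and Rps19-ps6. Mouse epithelial or dendritic cells are argued against, since Malat1 lay at 0.0586 of its T-like level and B2m at 5.25% of it. A candidate explanation is that these are cells of another species whose transcripts were counted on similar mouse sequences, such as pseudogenes without introns. The species was not tested, and no biological explanation from the design was tested for the difference between the libraries.

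The 24 genes found by the fixed rule in T-like cells had a median absolute log2 ratio of 0.46. After the trend of the ratios on transcript length was subtracted it was 0.44 (quartiles 0.39 and 0.51). The trend ran only from log2 -0.02 in the shortest transcripts to 0.12 in the longest, and the genes were picked for large ratios. Its subtraction could therefore change the median little whatever the cause, so this test cannot decide. The trend itself remains in the data. Among cells with 1.0 to 1.5% mitochondrial UMIs, 1342 Control and 1226 SAP cells, the median in the original direction was 0.43 (quartiles 0.36 and 0.63). For these genes as a set, that argues against the mitochondrial share of single cells as the whole cause. These cells are part of those in which the genes were picked. The test does not reach a difference in quality between whole libraries. What stays open is an effect of transcript length on single genes, a difference between the libraries in preparation or sequencing, and an effect of the phages. The last 2 cannot be told apart with 1 library per group.

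In cluster 9 the low Ccl4 and Il22 ratios may come from a few Control cells with very many UMIs. Without the 3 cells with most UMIs of the gene in each library the Ccl4 ratio was 1.06 (0.511 to 2.22), which restates that 116 of its 140 Control UMIs were in 1 cell and leaves the cause open. The Il22 ratio was 0.373 (0.231 to 0.585) without them, and with 21 Control and 17 SAP cells holding any Il22 UMI the cells are too few to decide. An effect of the phages on these genes stays open and untested.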

How the results depend on the processing

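The alternatives that added the shallow cluster, subtracted the length trend, took cells with 1.0 to 1.5% mitochondrial UMIs, left out 3 cells per gene, took CD8 cells by UMIs, or took list medians in other CD4 cells, and the count of shallow cells, were chosen after seeing the data. With 1 library per group no paired analysis was possible and no library could be left out. Of 701 recomputed log2 ratios of genes named in T-like cells 607 stayed within their intervals, 89 moved beyond them and 5 with an interval on 1 side turned to the other; of 287 list medians the numbers were 247, 35 and 5, of 64 thinned shares 59, 5 and 0, of 115 ratios of genes named in clusters 108, 4 and 3, of 32 cluster shares 25, 6 and 1, and of 12 ratios of other cell markers 5, 5 and 2. The numbers of cells passing the filters and of list medians outside the random range kept within 1.5 times under every alternative, and so did the number of genes 2-fold apart in cluster 9. Which lists lay outside did change. In CD4 T-like cells alone the NF-kB (percentile 54.89), anti-apoptosis (82.6) and apoptosis (3.125) lists lay inside. Outside there were the regulatory T cell (0), cytokine (0.02), oxidative phosphorylation (0.88), Th2 (1.9, 3 members) and antiviral sensing (97.53) lists. In T-like cells 8 genes were at least 1.5-fold higher, 2 lower and 0 at least 2-fold apart. These numbers were 2 higher and 6 lower with TMM scaling, and 5 and 4 with median-of-ratios scaling; these factors move all ratios together, so genes near 1.5-fold pass from one side to the other. They were 15 higher, 6 lower and 3 at 2-fold without mitochondrial, ribosomal and the 20 highest genes, a setting that also raised the eligible genes from 5399 to 6863. With eligibility at 5 CPM they were 117 higher, 28 lower and 16 at 2-fold, and at 50 CPM 1 higher and 0 lower, since each limit sets how many genes of low count enter. The mean of CPM per cell gave 23, 6 and 1, and thinning each cell to 1000 UMIs gave 56, 8 and 2. All cells passing filters gave 291 higher, 8 lower and 230 at 2-fold, and cells with a UMI of Cd3d, Cd3e or Cd3g gave 254, 6 and 216; both include cells of cluster 10. Clusters weighted equally gave 5 lower and 2 at 2-fold, the mitochondrial limit of 5% gave 1 lower, and keeping doublets gave 1 at 2-fold. Subtracting the trend on transcript length gave 4 higher, and T-like cells with 1.0 to 1.5% mitochondrial UMIs gave 50 higher, 32 lower and 6 at 2-fold. CD8 cells taken by UMIs gave 12 higher, 1 lower and 1 at 2-fold. The T-like share, 86.8% in Control and 85.1% in SAP, depended on where the shallow cells fell: it was 98.5% and 98.0% at Leiden resolution 0.4, 98.2% and 97.7% at resolution 1.2, 98.0% and 97.1% with the larger number of variable genes, 98.7% and 98.4% with a mitochondrial limit of 5%, 91.4% and 87.3% with a limit of 20%, 97.9% and 96.9% with doublets kept, 97.1% and 96.4% for cells with a UMI of Cd3d, Cd3e or Cd3g, and 98.4% and 98.0% with the shallow cluster added. It was lower in SAP in each. Of the shallow cells left by the filters, 49.4% of Control and 40.1% of SAP ones were T-like at the limit of 20%, and 98.2% or more in the other clusterings of these. The CD4 T-like share, 6.90% and 6.77%, was 4.12% and 4.31% at resolution 1.2 and 3.83% and 4.02% with CD4 cells taken by UMIs, so its direction is open. The log2 ratio of Trdc, 0.09, was -0.0110 in all cells and -0.00327 in cells with a UMI of Cd3d, Cd3e or Cd3g. Gzma, at -0.03, was at 0.00848 with clusters weighted equally, and in cells with 1.0 to 1.5% mitochondrial UMIs Gzma was at 0.10 and Gzmb at 0.0887, from -0.04. Among list medians, apoptosis and p53 was 0.0296 with eligibility at 5 CPM and 0.00221 in CD8 cells taken by UMIs, from -0.05, T follicular helper 0.10 after thinning, from -0.12, and in CD4 T-like cells alone NF-kB and TNF signalling was 0.00627 and anti-apoptosis and survival 0.0934, from -0.06 and -0.08. The cytokine list in cluster 9, at -0.20, was 0.0664 in CD4 cells taken by UMIs. With doublets kept the share of cluster 8 was at 0.19, from -0.26, and epithelial markers at 0.20, from -0.22, with 0.43 in cells with a UMI of Cd3d, Cd3e or Cd3g. Within clusters, Il22 in cluster 9, at -2.12, was 0.48 with CD4 cells taken by UMIs; without the 3 cells with most UMIs of the gene, Igha in cluster 5 was -2.82, from 2.96, and Ccl4 in cluster 9 was 0.0895, from -1.95, which lay in those cells. For the other changes the cause was not tested. List medians in a CD8 T-like cluster were not run because no cluster met the CD8 name, so CD8 cells taken by UMIs were set against all T-like cells.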

Other observations

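The list medians in cluster 9 were an alternative set before the data were examined; those in CD4 cells taken by UMIs, those without cells with transcripts of other T cell classes, the 6 genes of other classes and the sums of receptor families were chosen only after results were seen. In cluster 9, the CD4 T-like cells, the regulatory T cell list stood lower in the SAP library: 7 of 13 measured members were over 1.2-fold lower and 1 higher, and the median ratio was 0.769, at percentile 0 of the random lists. Il2ra, the high-affinity interleukin receptor chain, had a ratio of 0.471 (0.275 to 0.783) and was found in 10.8% of Control and 4.68% of SAP cells of the cluster. Foxp3, the lineage regulator, had a ratio of 0.532 (0.284 to 0.962), in 5.86% and 3.24% of cells, Ikzf2 0.769 (0.659 to 0.898) and Il10 0.550 (0.396 to 0.758), with 23 of 116 Control UMIs in 1 cell and a UMI in 8.95% of Control and 9.71% of SAP cells, while Ctla4 was at 0.956. Foxp3 rested on 36 UMIs in 19 Control cells and 18 UMIs in 9 SAP cells, and Il2ra on 35 and 13 cells. UMIs of 1 cell are not independent, so the intervals do not cover the spread between cells. Members of the list may sit in the same few cells, which random lists do not copy, so the percentile does not measure that spread. The shares of cells are not thinned and have no background share, so they describe each library. With CD4 cells taken by UMIs, many of them the same cells, the list median was -0.42 on the log2 scale. The cytokine list had a median ratio of 0.873 in cluster 9 but 1.05 in CD4 cells taken by UMIs.

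In the same cluster, 6 of 15 measured genes of tissue residency and gut homing were over 1.2-fold higher in SAP and 0 lower, with a median ratio of 1.13, at percentile 97.3, just inside the central 95% of random lists; in CD4 cells taken by UMIs it was 1.16, at percentile 98.2, outside them. Itga1, a collagen-binding integrin chain, had a ratio of 2.35 (1.43 to 3.98) and was found in 5.86% of Control and 11.5% of SAP cells, Itgae 1.58 (1.11 to 2.25), Jaml 1.61 (1.07 to 2.45) and Rgs2 1.41 (1.18 to 1.69). The shares of Itga1 are not thinned and have no background share. Of 6 genes of other T cell and NK classes looked at in the cluster, 4 were higher in SAP: Trdc had a ratio of 2.16 (1.43 to 3.31), Cd8b1 1.99 (15 UMIs in Control and 28 in SAP), Cd160 1.63 (1.02 to 2.63) and Tyrobp 13.8 (4.40 to 70.0), with 39 UMIs in 10 SAP cells and 3 in 3 Control cells, while the intervals of Cd8a, 1.28 (0.726 to 2.26), and Klrd1, 1.45 (0.623 to 3.49), held 1. The immediate early list lay at percentile 99.8 and the mitochondrially encoded list at percentile 99.2, both higher in SAP, while the cytotoxic and NK receptor list lay inside the random range, at percentile 88.9, and at 99.6 in CD4 cells taken by UMIs. Without the cells that held a UMI of Cd8a, Cd8b1, Trdc or Tyrobp, which left 283 Control and 225 SAP cells, the median log2 ratio was -0.45 for the regulatory list, at percentile 0, and 0.24 for the residency list, at percentile 99.4. These values come from 1 library per group, with no replicate check.

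Receptor segments and Ly49 receptors in T-like cells showed small differences that went both ways. Variable segments of the gamma chain had a summed ratio of 1.11 (1.05 to 1.18), with Trgv2 at 1.11 and Trgv4 at 13.1 CPM in Control and 17.1 CPM in SAP, delta segments 1.06, beta segments 1.05 (0.933 to 1.18) and alpha segments 0.822 (0.746 to 0.904). The Ly49 gene Klra7 had a ratio of 1.29 (1.13 to 1.46) and Klra6 stood at 17.6 and 21.0 CPM, whereas Klra3 had a ratio of 0.723 (0.582 to 0.897) and Klra5 1.01. These genes belong to families of similar sequence, so reads could be split between members.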
